A study of Mus musculus with 13 samples.

How the data were processed

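RNA was taken from mandibular condylar cartilage of young (2 months) and aged (18 months) mice, 7 and 6 libraries. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was captured on oligo(dT) beads, and paired, strand-specific reads were made on a DNBSEQ instrument. Per the submitters' processing notes, HISAT2 2.1.0, Bowtie2 2.3.4.3, RSEM 1.3.1 and DESeq2 1.4.5 were used with the mouse build GRCm39. The notes give no roles or order, and the annotation is not given in the sources used here. Per the file headers, the authors deposited 1 table of 18748 genes with a read count column for each library, which holds expected counts, since 5.3% of its values were not whole. The same deposited table gives FPKM and TPM for each library, which the authors normalised by gene length and depth. It names genes by symbol and gene ID, 18609 of which were also in a RefSeq gene table of another build (GRCm38.p6), so no coordinates are given.

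Libraries were grouped by the age in their titles. Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15) and library sizes were scaled by TMM. Aged was compared with young by the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) in all 13 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count asked for a change of at least 2-fold. Levels are TMM-normalised CPM as mean ± SD, and the SE of a log2 fold change is its size divided by the square root of the F statistic. Log2 CPM values for lists used a prior count of 2.

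The 44 gene lists were fixed before the data were examined, 42 of which had at least 3 tested members. Of the others, the mitochondrially encoded list had 0 tested members and the salivary gland list 2. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01), and beside it with an estimated correlation, with fry and with a two-sided exact permutation test of each library's mean over members across all 1716 splits, whose smallest p is 0.000583. The spread within a group was the root mean squared distance of a library from its group mean, corrected for group size. It was compared by a permutation test over the same splits, with the distances held fixed.

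Named genes followed a rule also fixed beforehand, which left out predicted, ribosomal protein, histone and immune receptor genes. It took the 10 largest rises and 10 largest falls among called genes with a mean FPKM of at least 5 and no overlap between ages. From each list it took the 2 called members with the largest change in the direction of most called members and the 1 largest in the other direction, or, where none was called, the member with the highest level. It added 13 genes of interest to cartilage ageing, of which those measured are given. Genes outside it are named as such. Some genes the rule took are not reported here, alone or under the alternatives.

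The alternatives were no filter or a stricter one, library sizes alone, RLE, quantile and TPM scaling, limma on log2(FPKM + 1) and log2(FPKM + 0.1), limma-voom with and without library weights, DESeq2 1.42.0, a replicate block, marker scores as covariates and each library left out in turn. The scripts were tested on simulated counts for 14067 genes drawn from the real means, dispersions and library sizes. Of 50 genes changed at each size, 66% were recovered at 1.5-fold, 86% at 2-fold, 98% at 4-fold and 100% at 8-fold, and 4.76% of calls were false. Both shifted lists of 20 genes were recovered and none of the other 18 was called. The genes were simulated independently of one another, and far fewer were changed than were called in the data. The single genes changed left out the lowest-expressed ones. This run therefore does not test list calls where members vary together (estimated correlation up to 0.93 in the real lists). Libraries within an age were compared by chi-square over genes for duplicates (smallest value per degree of freedom 10.2). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A depth of at least 16356839 counts per library leaves the spread between libraries, not counting error, as the main error for the genes named, except those near 1 CPM.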

Results

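Messenger RNA was sequenced from the mandibular condylar cartilage, the tissue that covers the jaw side of the temporomandibular joint. There were 7 libraries of young mice (2 months old) and 6 of aged mice (18 months old). The labels number the libraries and do not say whether each came from 1 mouse. The deposited expected counts summed to between 17531694 and 18203443 per library in the young mice and between 16356839 and 17876681 in the aged mice. The mean depth was lower in the aged mice by a two-sided exact permutation test (p = 0.00641). Of the 18748 genes in the table, 14067 had enough counts to be tested. Ddx3y, a Y-linked gene, was detected in each of the 13 libraries at 66.8 ± 3.22 CPM (TMM-normalised; SD, n = 7) in young and 60.8 ± 5.83 CPM (SD, n = 6) in aged mice. No pair of libraries within an age agreed within sampling noise, so no duplicate was found. This does not show that the libraries came from different mice, and each was counted as 1 replicate.

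The study asks which genes differ between young and aged condylar cartilage. Most collagens and the matrilins of cartilage matrix were much lower in the aged mice, while a smaller set of matrix genes was higher. Col9a1 (gene ID 12839), a chain of the type IX collagen on the surface of cartilage fibrils, went from 534.3 ± 101 CPM (SD, n = 7) to 15.96 ± 10.9 CPM (SD, n = 6), a log2 fold change of −5.06 ± 0.43 (SE, edgeR adjusted p = 1.27e-06). Cnmd (gene ID 16840), which encodes the vessel-repelling cartilage protein chondromodulin, went from 25.7 ± 10.7 to 0.587 ± 0.664 CPM (0.33 without aged replicate 1), a log2 fold change of −5.40 ± 0.50 (SE, edgeR adjusted p = 2.55e-06). Cytl1 (gene ID 231162), a secreted protein made by chondrocytes, moved the other way, from 13.4 ± 2.77 to 249.8 ± 124 CPM (log2 fold change 4.22 ± 0.34, SE, edgeR adjusted p = 8.25e-07).

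Of the 21 tested members of the cartilage matrix list, 13 fell, 6 rose and 2 were not called, and the counts were the same adjusted over the list alone. Col2a1, the main collagen of cartilage, fell from 25340 ± 5037 CPM (SD, n = 7) to 6836 ± 3143 CPM (SD, n = 6), a log2 fold change of −1.89 ± 0.24 (SE, edgeR adjusted p = 3.6e-05). Matn3, a matrilin that links cartilage fibrils, fell by 4.22 on the log2 scale, and the type IX chains Col9a3 and Col9a2 fell by 2.69 and 2.14. Chad (chondroadherin), Ucma, Comp and Prelp, singled out after their values were seen, rose by 2.05, 1.18, 1.02 and 0.95 on the log2 scale. Acan, the core protein of aggrecan, was at 2119 ± 469 CPM in young and 2039 ± 524 CPM in aged mice. Its log2 fold change of −0.06 ± 0.18 (SE) was not called (edgeR adjusted p = 0.821) and was above 0 with library sizes alone, quantile scaling or the TPM scale. Sox9, the transcription factor that drives chondrocyte identity, had a log2 fold change of 0.11 ± 0.13 (SE, edgeR adjusted p = 0.501). With library sizes alone it was 0.34 (adjusted p = 0.0289). Among 12 chondrogenic regulators, 4 rose and 3 fell, the same adjusted over the list alone. Fgfr3, a receptor that restrains chondrocyte growth, was the largest fall at −1.09 ± 0.12 (SE), and Nkx3-2 rose by 1.05. The cartilage matrix list as a whole was lower by limma's camera (adjusted p = 0.00994) and by an exact permutation test of library means (adjusted p = 0.00204), with adjusted p = 0.51 under camera with an estimated correlation. The camera call was lost with the erythroid and neutrophil score as a covariate (median −1.10, adjusted p = 0.0628) and with both marker scores (0.114).

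**Figure D1:**
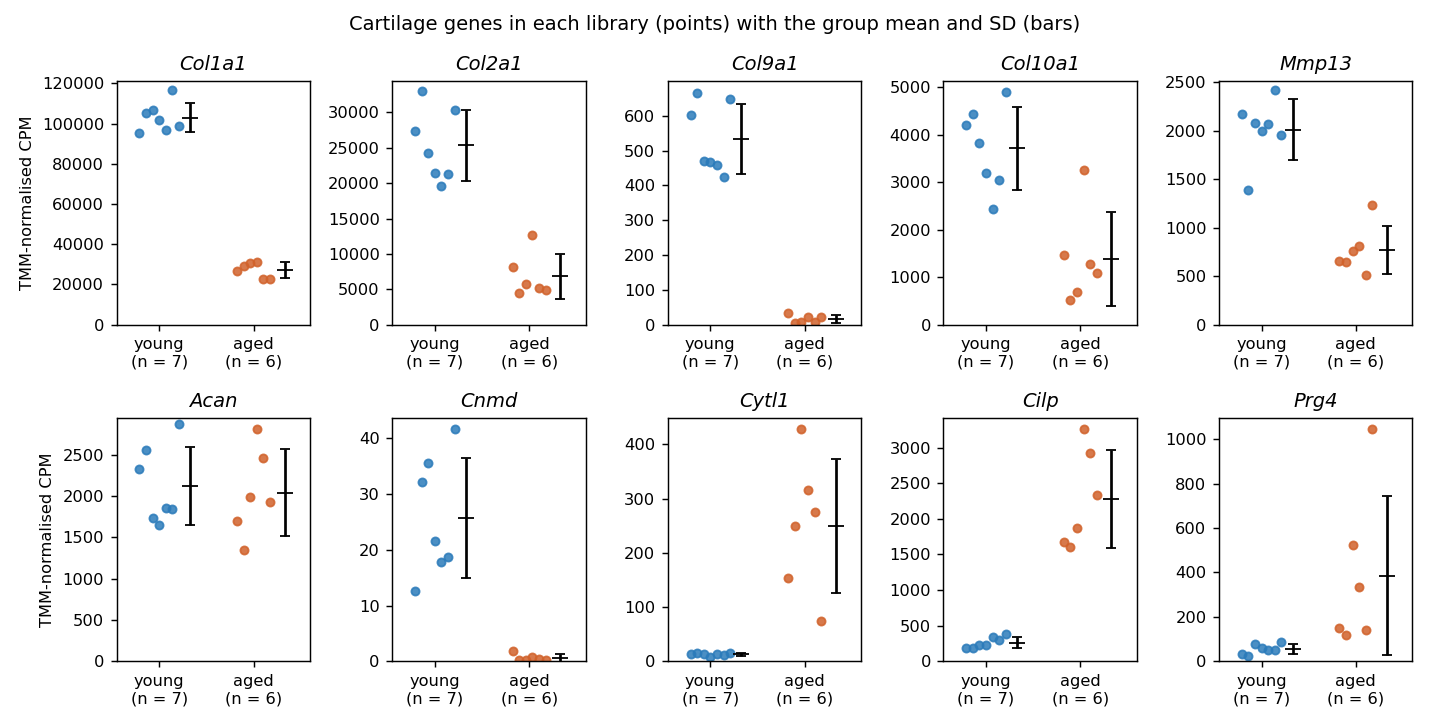
Expression (TMM-normalised CPM, vertical axes) of 10 cartilage genes in each young (n = 7, blue) and aged (n = 6, orange) library, with the group mean and SD as black bars. The 6 aged libraries lay below all 7 young libraries for Col1a1, Col2a1, Col9a1, Mmp13 and Cnmd and above them for Cytl1, Cilp and Prg4, while the ages overlapped for Acan and Col10a1.

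Genes of type I and other collagens and of collagen assembly were lower as well. Col1a1 and Col1a2, the chains of type I collagen, together took 18.0 ± 1.16% of all counts in young (SD, n = 7) and 5.80 ± 0.716% in aged libraries (SD, n = 6; two-sided exact permutation p = 0.000583, the smallest possible). Their log2 fold changes were −1.92 ± 0.11 and −1.81 ± 0.10 (SE, edgeR adjusted p = 4.66e-08 for both). In the list of fibrillar and basement membrane collagens, 10 of 15 members fell and none rose (11 fell adjusted over the list alone; camera adjusted p = 5.55e-06, adjusted p = 0.429 with an estimated correlation). Of 21 genes for collagen processing and cross-linking, 15 fell and none rose, the same adjusted over the list alone (camera adjusted p = 3.92e-07, adjusted p = 0.459 with an estimated correlation). They include Lox, the enzyme that starts collagen cross-linking, at −1.65 ± 0.17 (SE), and Pcolce2, which enhances procollagen cleavage, at −1.84 ± 0.22 (SE).

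Osteoblast and osteocyte markers fell in 12 of 15 cases and rose in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 4.7e-06, adjusted p = 0.429 with an estimated correlation). With the erythroid and neutrophil score as a covariate 6 fell and 1 rose, at a median of −0.80 against −0.79 without it. Bglap, which encodes osteocalcin and shares reads with its near-identical neighbours Bglap2 and Bglap3, so that its own level is uncertain, went from 1997 ± 264 to 553.5 ± 245 CPM. Osteoclast markers fell in 11 of 14 cases and rose in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 3.37e-05, adjusted p = 0.487 with an estimated correlation). Ocstamp and Dcstamp, which act in osteoclast fusion, stood at −1.44 ± 0.10 and −1.15 ± 0.15 (SE), and Nfatc1, the main osteoclast transcription factor, at 0.31 ± 0.07 (SE). Only 4 markers fell with the erythroid and neutrophil score as a covariate (median −0.49 against −0.83 without it), and Dcstamp then stood at −0.68 (edgeR adjusted p = 0.0805). With both scores the median was −0.24 and the list was not called (camera adjusted p = 0.366). Among 15 genes of hypertrophic chondrocytes 7 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.494 with an estimated correlation). Only 3 fell with the erythroid and neutrophil score as a covariate, and the call was lost (median −0.39 to −0.26, adjusted p = 0.268). Of the 7 that fell without it, Ibsp, Runx2 and Sp7 are also counted among the osteoblast markers and Mmp13 among the proteases. Col10a1, the collagen specific to hypertrophic cartilage, went from 3714 ± 871 to 1381 ± 989 CPM, and Mmp13, a collagenase, from 2010 ± 315 to 770 ± 249 CPM. The log2 fold change of Col10a1 was −1.43, and its call was lost with the muscle score (−1.10, adjusted p = 0.139) and with the erythroid and neutrophil score (−2.12, adjusted p = 0.113).

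Some genes typical of the joint surface and 2 protease inhibitors were higher in aged cartilage. Cilp, a protein of the cartilage intermediate layer, rose from 264.5 ± 77.3 CPM (SD, n = 7) to 2277 ± 692 CPM (SD, n = 6), and Prg4, which encodes the lubricant lubricin, from 55.3 ± 22.3 to 385.8 ± 358 CPM (254 without aged replicate 6). In the superficial zone and fibrous layer list 6 of 17 members rose and 2 fell (7 and 2 adjusted over the list alone). Its median was 0.34, and 0.12 with the muscle score or 0.073 with the erythroid and neutrophil score as a covariate. The list was not called by camera (adjusted p = 0.123, and 0.638 with an estimated correlation). It passed the exact permutation test (adjusted p = 0.00941), which does not compare it with other genes. Of 17 matrix proteases and inhibitors 9 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.00385, adjusted p = 0.429 with an estimated correlation). The proteases Mmp16 and Adamts9 fell by 2.08 and 1.56 on the log2 scale, and the aggrecanase Adamts5 fell by 0.52 (0.034 with the erythroid and neutrophil score as a covariate, adjusted p = 0.899). The 2 members that rose were both inhibitors of metalloproteinases, Timp4 at 2.19 ± 0.32 and Timp3, named after its value was seen, at 1.23 ± 0.18 (SE). Timp4 stood at 1.08 with the muscle score as a covariate.

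Growth factor and signalling genes moved with age too. In the growth factor and IGF axis list 9 of 15 members fell and 2 rose, the same adjusted over the list alone (camera adjusted p = 0.00769, adjusted p = 0.429 with an estimated correlation). The imprinted gene Peg3 fell from 236.3 ± 23.4 CPM (SD, n = 7) to 64.1 ± 11.4 CPM (SD, n = 6), and Igf2 and Igf1, growth factors named here after their values were seen, fell by 1.41 and 1.09 on the log2 scale. Hedgehog pathway members fell in 8 of 12 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 0.0147, adjusted p = 0.494 with an estimated correlation). Under the erythroid and neutrophil score as a covariate no member was called and the median moved from −0.34 to 0.024. With library sizes alone 3 hedgehog members fell and 1 rose, at a median of −0.11. The hedgehog-binding protein Hhip stood at −1.42 ± 0.25 (SE). Of 22 Wnt pathway genes 9 fell and 5 rose (10 and 5 adjusted over the list alone; camera adjusted p = 0.0403, adjusted p = 0.459 with an estimated correlation). Among them, the Wnt antagonists Dkk2 and Frzb stood at −1.69 ± 0.16 and −1.13 ± 0.17 (SE). The Wnt call was lost without young replicate 2, aged replicate 1 or aged replicate 6 (camera adjusted p between 0.0519 and 0.0584) and with the erythroid and neutrophil score as a covariate (0.268). In the TGF-beta and BMP list, which was not called (camera adjusted p = 0.866), Ltbp2, a matrix protein of the latent TGF-beta binding family, rose by 2.09 and Id3, a BMP target, fell by 0.83. The cell cycle inhibitor Cdkn2a rose from 2.52 ± 0.594 to 5.96 ± 2.81 CPM and Cdkn1a fell from 255.2 ± 25.8 to 160.2 ± 15.4 CPM. Cdkn2a lost its call with the muscle score as a covariate (log2 fold change 1.24 without and 0.88 with it, adjusted p = 0.119), and Cdkn1a with the erythroid and neutrophil score (−0.67 and −0.37, adjusted p = 0.078). The list of senescence and secreted inflammatory genes had 6 members that rose and 4 that fell of 20, the same adjusted over the list alone. It was not called by camera (adjusted p = 0.662). The list passed the exact permutation test (adjusted p = 0.00918), which does not compare it with other genes.

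Clock genes moved apart between the ages. All 18 tested members of the circadian clock list were called, 13 higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.00769, adjusted p = 0.494 with an estimated correlation). Hlf, an output transcription factor of the clock, and Ciart, a repressor, rose by 2.18 ± 0.30 and 2.03 ± 0.26 (SE), and Dbp and Per2 rose by 1.97 and 1.91. Npas2 and Arntl, partners in the activating complex, had log2 fold changes of −1.78 ± 0.24 and −1.37 ± 0.13 (SE). Dbp, Per2 and Arntl were named after their values were seen. With library sizes alone 13 members were called higher and 3 lower, and the list was no longer called by camera (adjusted p = 0.184). Its median moved from 1.19 to 1.42 there, while the median of all tested genes moved from 0.014 to 0.24.

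**Figure D2:**
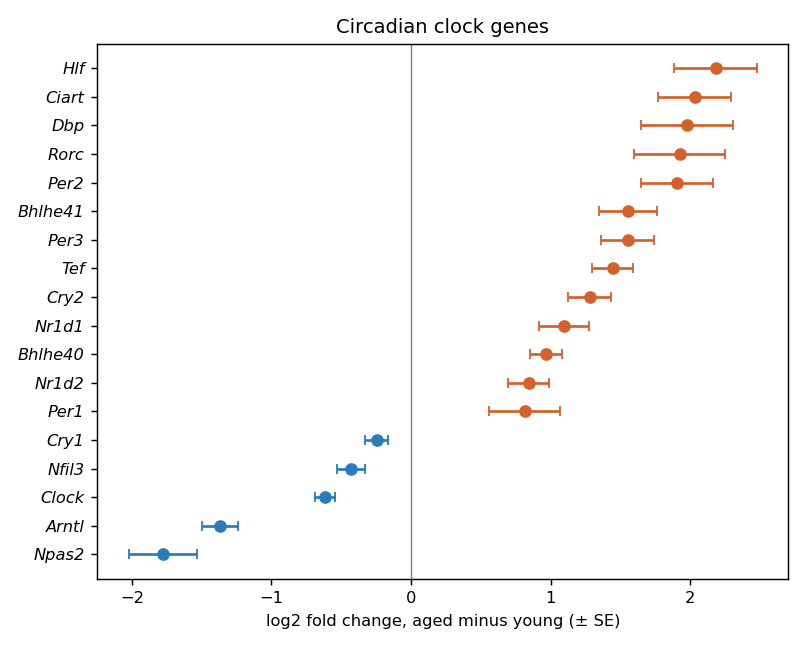
Log2 fold change (aged minus young, horizontal axis) with its SE (bars) of the 18 circadian clock genes from the edgeR fit of 7 young and 6 aged libraries, rising genes in orange and falling genes in blue. Npas2 at −1.78 and Hlf at 2.18 mark the ends of the range.

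Markers of blood, muscle and other cells were higher in the aged libraries. All 14 erythroid markers rose, the same adjusted over the list alone (camera adjusted p = 1.96e-08, adjusted p = 0.459 with an estimated correlation). Their median log2 fold change was 3.63. Haemoglobin genes, whose near-identical copies were summed, took 0.0640 ± 0.0386% of counts in young (SD, n = 7) and 0.739 ± 0.409% in aged libraries (SD, n = 6; two-sided exact permutation p = 0.000583, the smallest possible). Slc4a1 (the band 3 anion exchanger), Epb42, Hemgn and Rhag stood among the 10 named genes with the largest rise, with log2 fold changes from 3.76 to 3.87, beside Ermap and Trim10. Skeletal muscle markers rose in 16 of 18 cases (17 adjusted over the list alone; camera adjusted p = 3.54e-05, adjusted p = 0.5 with an estimated correlation). They took 0.285 ± 0.226% of counts in young and 1.48 ± 0.749% in aged libraries (two-sided exact permutation p = 0.000583). Neutrophil markers rose in 11 of 13 cases, the same adjusted over the list alone (camera adjusted p = 0.00425, adjusted p = 0.51 with an estimated correlation; with library sizes alone 0.181), including Mpo at 1.83 ± 0.35 (SE). All 7 tested mast cell markers rose, the same adjusted over the list alone (camera adjusted p = 0.000332, adjusted p = 0.429 with an estimated correlation). Levels were low, with Cma1 at 0.212 CPM in young and 1.39 in aged libraries and Ms4a2 at 0.445 and 2.34. Genes this low in young libraries pass the filter mainly through the aged ones, which favours rises. With the erythroid and neutrophil score as a covariate 4 markers rose and the median moved from 2.13 to 1.09.

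Replication and respiration genes were higher beside these markers. Of 20 DNA replication genes 19 rose, the same adjusted over the list alone (camera adjusted p = 1.04e-06, adjusted p = 0.494 with an estimated correlation). The licensing factors Cdc6 and Mcm2 stood at 1.75 ± 0.27 and 1.20 ± 0.17 (SE). With the erythroid and neutrophil score of each library as a covariate none of them was called and the median moved from 0.83 to −0.01. Mki67, a marker of dividing cells, rose by 1.05 ± 0.26 (SE), and under the same covariate its log2 fold change was −0.61 (edgeR adjusted p = 0.18). The 30 nuclear genes of oxidative phosphorylation included 25 that rose (27 adjusted over the list alone; camera adjusted p = 2.98e-05, adjusted p = 0.51 with an estimated correlation). Cox5a and Ndufv1 rose by 0.81 and 0.80. With the muscle score as a covariate none was called and the median moved from 0.53 to 0.07. Glycolysis and hypoxia genes rose in 13 of 22 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.000664, adjusted p = 0.487 with an estimated correlation). The hexokinase Hk2 stood at 1.398 ± 0.18 (SE). With the muscle score as a covariate 6 members rose and Hk2 stood at 0.76, while the list median hardly moved (0.39 to 0.34) and the list stayed called by camera. The collagens kept their direction under both covariates taken singly. Col1a1 stood at −2.003 with the muscle score and −1.70 with the erythroid and neutrophil score, Col9a1 at −4.47 and −6.51, and Col2a1 at −1.74 and −2.05.

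**Figure D3:**
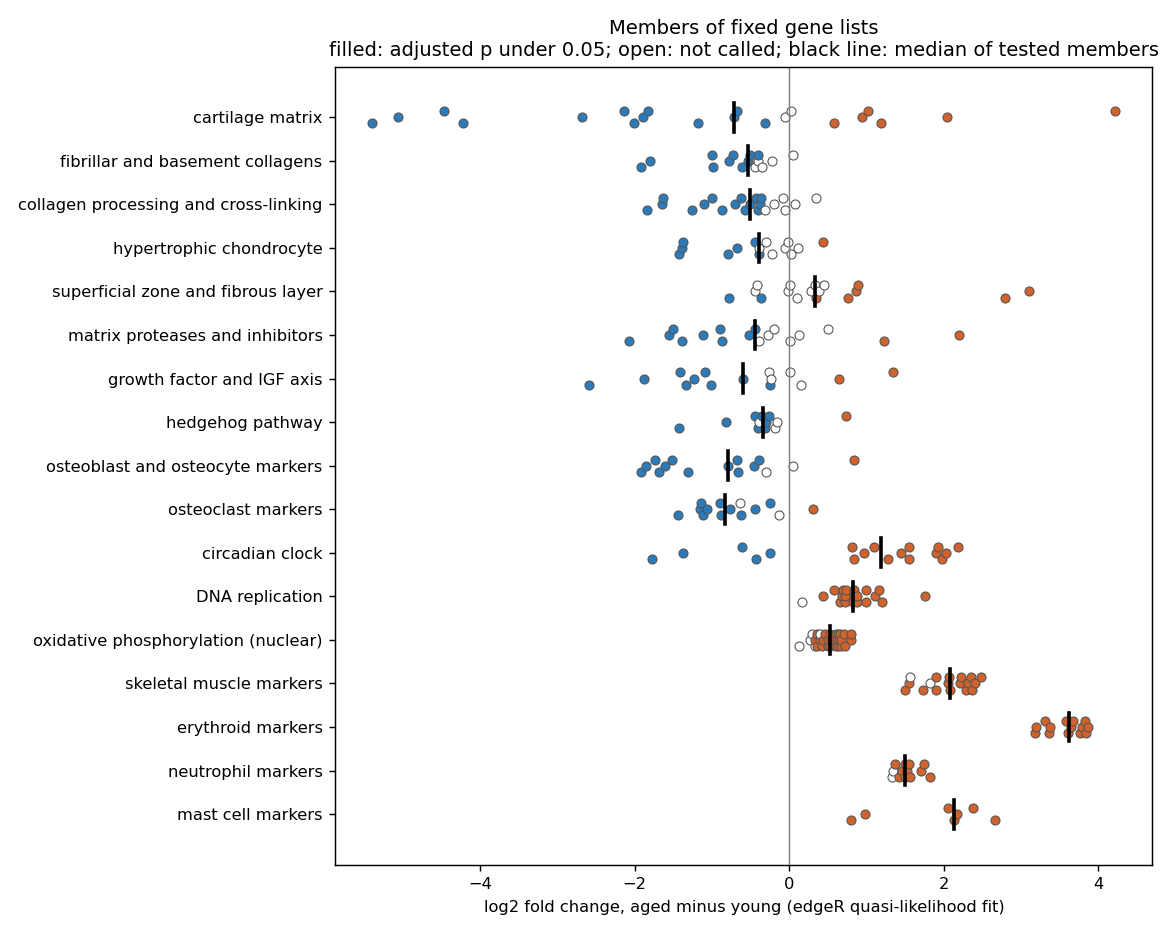
Log2 fold change (aged minus young, horizontal axis) of each tested member of 17 gene lists (rows), from the edgeR fit of 7 young and 6 aged libraries. Filled points passed the adjusted threshold of 0.05, open points did not, and black lines mark medians, which run from −0.83 for osteoclast markers to 3.63 for erythroid markers.

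In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6504 of the 14067 genes were called, 3471 higher and 3033 lower in aged cartilage, and 1625 of them changed at least 2-fold (1219 higher and 406 lower). The aged and young libraries did not overlap for 2695 genes, 19.2% of those tested, where chance gives 0.117%. Library sizes in place of TMM factors moved the median log2 fold change of all tested genes to 0.24 and the split to 7034 higher and 1253 lower, quantile scaling gave 2621 higher and 4005 lower, and the TPM scale 3883 and 2211. The count dropped to 3611 with the muscle score as a covariate, 2912 with the erythroid and neutrophil score and 41 with both, scores that themselves follow age (r = 0.766 and 0.876 with the age group).

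Of 42 tested gene lists, 23 were called by camera with its preset correlation of 0.01, 13 higher and 10 lower. The exact permutation test of list means called 33. That test does not compare a list with other genes, and 46.2% of all tested genes were called. A list can therefore pass it without differing from other genes. Under camera with an estimated correlation no list was called (smallest adjusted p = 0.429), although 4 had an unadjusted p under 0.05. The preset correlation also called a median of 13 lists in 99 other splits of the libraries into groups of 7 and 6, so the camera calls on their own do not separate age from other groupings.

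Libraries of aged mice lay farther apart than those of young mice. The root mean squared distance of a library from its group's mean over all tested genes was 0.293 ± 0.0372 (log2, SD, n = 7) in young and 0.376 ± 0.0590 (log2, SD, n = 6) in aged mice. The difference of 0.0829 passed a two-sided permutation test over all splits (p = 0.0105). The distances were not recomputed for each split, so this p-value is approximate. Single libraries stood apart from their group for some named genes: young replicate 1 for Mcm2, young replicate 2 for Nkx3-2 and Mmp13, young replicate 6 for Dkk2 and young replicate 7 for Cdkn2a. Among the aged libraries this held for replicate 2 in Hhip, replicate 4 in Lox and replicate 6 in Peg3. Such libraries were found in 18 of 352 groups of values (5.11%), where chance gives about 1 in 20.

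**Figure D4:**
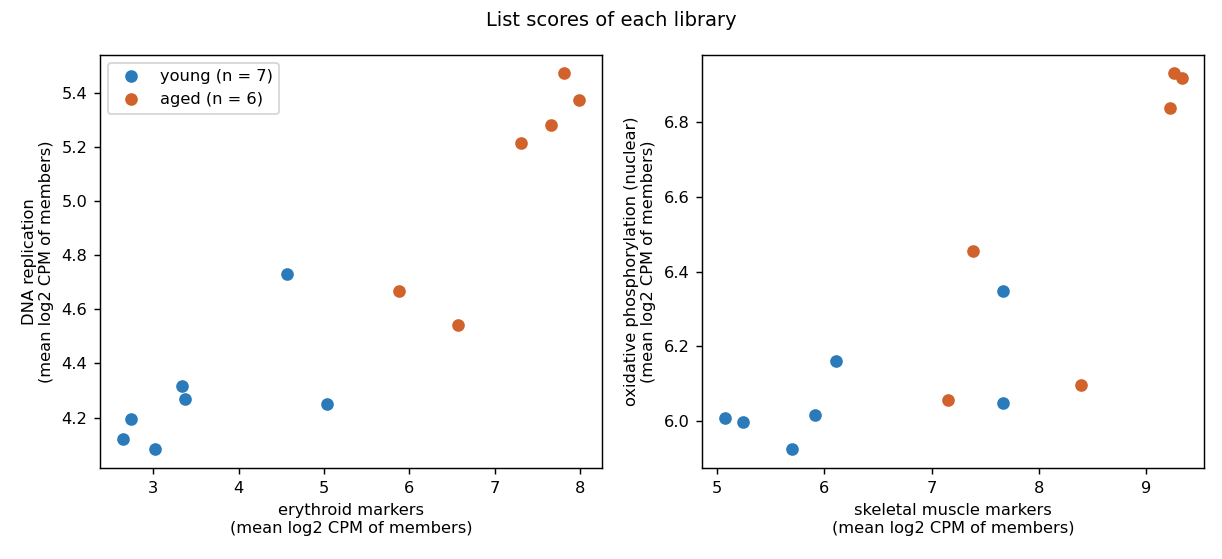
Mean log2 CPM of the DNA replication list against erythroid markers (left) and of the oxidative phosphorylation list against skeletal muscle markers (right), 1 point per library, young (n = 7) in blue and aged (n = 6) in orange. The erythroid score was 3.53 ± 0.921 in young and 7.204 ± 0.820 in aged libraries (mean and SD).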

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

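The tests on collagens, replication and respiration genes, clock genes and other splits of the libraries were chosen after the values they use had been seen.

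The collagens as a set were lower in aged cartilage, with 17 of 22 tested members called lower and 0 higher. Dilution by muscle alone or by blood and marrow cells alone would end most of these calls once its score is a covariate. With the muscle score 13 of the 17 remained called lower, and with the erythroid and neutrophil score 11 did. Their medians were −1.07 and −1.28 against −0.996 without. A few genes taking most counts would lose the pattern with library sizes alone, where 14 remained called lower, and 14 of 15 did with Col1a1 and Col1a2 taken out of the counts. A first comparison, the median of the other cartilage matrix members minus that of the collagens, was 0.74 with a bootstrap SE of 0.771 and decided nothing. What stays open is dilution by both tissues together, a changed mix of cartilage and bone cells, and age itself. The mix and age were not tested, and scores that follow age cannot exclude such dilution. With both scores in the fit only 41 genes in all were called, and 0 of 15 fibrillar and basement membrane collagens. Their median was −0.68 (−0.54 without), with a median SE of 0.43 (0.15 without). Of 21 cartilage matrix members 1 was called lower and 1 higher there. Col1a1, Col2a1 and Col9a1 stood at −1.74, −1.80 and −5.64 (edgeR adjusted p = 0.0871, 0.305 and 0.0212).

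Higher DNA replication genes may come from erythroid precursors, and higher oxidative phosphorylation genes from muscle, whose markers share 0 genes with other lists. With the erythroid and neutrophil score as a covariate the replication median was −0.0087 (0.83 without). With the muscle score the respiration median was 0.068 (0.53 without). The first score also holds neutrophil markers, so that fit does not single out erythroid cells. Both scores follow age so closely that these shifts cannot be told apart from an age effect. Replication against the erythroid score gave r = 0.612 in young (n = 7, exact permutation p = 0.141, adjusted 0.141, rho = 0.643, p = 0.139, adjusted 0.139, r = 0.712 without the 2 farthest libraries) and r = 0.917 in aged mice (n = 6, exact p = 0.0236, adjusted 0.0944, rho = 0.886, p = 0.0333, adjusted 0.0455, r = 0.778 without 2). Respiration against the muscle score gave r = 0.66 in young (exact p = 0.076, adjusted 0.104, rho = 0.821, p = 0.0341, adjusted 0.0455, r = 0.492 without 2) and r = 0.813 in aged mice (exact p = 0.0778, adjusted 0.104, rho = 0.886, p = 0.0333, adjusted 0.0455, r = 0.997 without 2). Over these 4 relations rho passed the threshold in 3 and Pearson's r in none after adjustment, so both explanations stay open, beside haemoglobin genes at 0.739% of counts in aged libraries.

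The opposite shifts of the 18 called clock genes are not accounted for by the scores taken singly: 12 remained called with the same sign with the muscle score and 12 with the erythroid and neutrophil score, though none did with both scores. A different hour of collection for each age remains a candidate explanation. It was expected to part the ages in every called member, and without it most were expected to overlap; 16 of 18 did not overlap, which meets neither, and an effect of age on the clock could do the same. The labels used here give no hour, so the 2 cannot be told apart.

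Chance is an unlikely source of the count of called genes: of 100 splits of the libraries into groups of 7 and 6, the real one included, 1 gave as many as 6504. The highest other gave 1919 and held 5 of the 6 aged libraries in 1 group, and the median of the others was 0. Only 100 of the 1716 splits were drawn, so the smallest share that could be found was 1 in 100. For changes of at least 2-fold 1 split reached 1625, and the highest other gave 553. Chance cannot be excluded for the count of lists called by camera, since 6 of the 100 splits gave 23 or more, and the highest other gave 26.

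Single libraries stood far from the rest of their group in 18 of 352 groups of values (5.11%), and chance gives about 1 in 20. In list scores (mean log2 CPM), young replicate 1 was at 4.73 for DNA replication (others 4.08 to 4.32), aged replicate 6 at 4.76 for senescence and secreted factors (4.29 to 4.45) and young replicate 4 at 6.52 for autophagy and lysosome (6.58 to 6.62). Aged replicate 2 was at 6.74 for antigen presentation (5.83 to 6.10), young replicate 5 at 5.65 for immediate early genes (4.84 to 5.19) and aged replicate 3 at 0.787 for B cell markers (3.06 to 4.19). The remaining values are log2 of CPM plus 0.5. Young replicate 1 was at 5.46 for Mcm2 and 1.72 for Rspo2, and young replicate 2 at 1.47 for Nkx3-2 and 10.4 for Mmp13. Young replicate 5 was at 6.34 for Plvap, young replicate 6 at 2.60 for Dkk2 and young replicate 7 at 0.884 for Cdkn2a. Aged replicate 2 was at 5.01 for Tfeb and 3.91 for Hhip, aged replicate 3 at 3.36 for Apol11b, aged replicate 4 at 8.88 for Lox and aged replicate 6 at 5.42 for Peg3.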

How the results depend on the processing

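The fits on RLE scaling, on log2 FPKM and with both scores as covariates were chosen after seeing the data. The count of called genes stayed between 4457 and 8287 under the filters, scalings and tools tried (6504 as reported), and 5888 to 6513 with each library left out. It was 3611 with the skeletal muscle score as a covariate, 2912 with the erythroid and neutrophil score and 41 with both; each score overlaps with age, and the cause was not tested. The count of changes of at least 2-fold (1625) was 1530 to 1678 with each library left out, 2129 with no filter, 2014 with DESeq2, 1921 with library sizes alone, 1443 with quantile scaling (895 higher and 548 lower), 681 under the stricter filter, which tests fewer genes, 823 on log2(FPKM + 1) and 1133 on log2(FPKM + 0.1), and 40 with both scores. Lists called (23) ranged from 20 to 27 with each library left out, were 0 under camera with an estimated correlation and 12 with both scores. With library sizes alone the antioxidant, clock, interferon, adipocyte and neutrophil lists lost their calls although their medians grew (to 0.67, 1.42, 0.55, 0.93 and 1.74). Of the named genes, 30 lost their call with the muscle score, 53 with the erythroid and neutrophil score and 114 with both. Among these, Nkx3-2 (0.62 and 1.25) and Nfatc1 (0.295 and 0.247) lost it with either score, and Prg4 (2.76), Npas2 (−0.88), Hhip (−1.52), Mpo (0.73), Slc4a1 (1.12), Hemgn (1.06), Rhag (1.54), Ermap (1.44) and Trim10 (1.04) with the erythroid and neutrophil score. Other changes moved but stayed called: with the muscle score Cytl1 (3.56), Hlf (1.41) and Ciart (1.35), and with the erythroid and neutrophil score Cytl1 (5.44), Cnmd (−4.28), Matn3 (−3.46), Col9a2 (−2.74), Adamts9 (−0.81), Ltbp2 (2.72) and Epb42 (1.22). The difference in spread (0.0829) ranged from 0.0655 to 0.102 with each library left out (permutation p between 0.00253 and 0.0379). With a replicate block, 5771 genes, 1522 of them at least 2-fold, and 27 lists were called in replicates 1 to 6. Same-numbered libraries of the ages correlated between −0.12 and 0.258, over 0.1 in 5 of 6 pairs, and 2 libraries correlated best with their own number, so the numbers were not taken as pairs. Depth limits the genes near 1 CPM most.

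Some values changed direction, and the cause was not tested. The exceptions are the neutrophil and skeletal muscle lists, which make up part of the scores, so their own shifts there follow from the fit. With the erythroid and neutrophil score the list medians (log2) were −0.90 for cell cycle, −0.23 for senescence, 0.11 for TGF-beta and BMP (only the camera direction turned), −0.73 for neutrophil, −0.37 for plasma cell, −0.0028 for macrophage and 0.32 for endothelial lists, and with the muscle score −0.21 for smooth muscle. With both scores they were −0.64 for cell cycle, −0.14 for senescence, −0.0256 for immediate early, −1.40 for neutrophil and −0.16 for plasma cell lists. Hedgehog (−0.026) and TGF-beta and BMP (0.024) turned there by camera alone. With library sizes alone the camera direction turned for chondrogenic regulators (median 0.35), senescence (0.59) and plasma cell markers (0.31). Chondrogenic regulators turned under fry (0.13) and without young replicate 3 or aged replicate 4 or 5 (0.0093 to 0.164 over all libraries left out). TGF-beta and BMP turned under fry and permutation (0.0077) and without aged replicate 1 or 6 (−0.045 to 0.046 over all), and plasma cell markers without aged replicate 6 (−0.074 to 0.197 over all). Some medians changed sign while the camera direction held. With the erythroid and neutrophil score these were antioxidant (−0.027), DNA replication (−0.0087), hedgehog (0.024), complement (−0.18) and autophagy (0.0124), with both scores interferon (−0.10), macrophage (−0.071) and skeletal muscle (−0.0159), and with the replicate block or the muscle score TGF-beta and BMP (−0.0126 and −0.03) and, with the block, plasma cell lists (−0.045).

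Among genes, the erythroid and neutrophil score gave Mki67 −0.61, Ube2c −0.67, Gclm −0.027, Rsad2 −0.0127, Acan 0.066 and Sox9 −0.12. Both scores gave Mki67 −0.27, Ube2c −0.30, Prtn3 −0.0155, Lyz2 −0.20, Des −0.22, Acan 0.23, Sox9 −0.20 and Adamts5 0.0305. Prtn3 is a neutrophil marker and so a member of the erythroid and neutrophil score. Acan was 0.17 with library sizes alone, 0.0901 with quantile scaling, 0.0163 on the TPM scale and 0.0135 with the replicate block. It was −0.174 to 0.0341 over all libraries left out, above 0 without young replicate 7 or aged replicate 2. Sox9 was −0.0212 to 0.169, below 0 without aged replicate 4, and Ddx3y 0.10 with library sizes alone.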

Other observations

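Several immune, stress and vessel genes also differed between the ages. Antigen presentation genes rose in 9 of 14 cases (11 adjusted over the list alone; camera adjusted p = 0.00738, adjusted p = 0.528 with an estimated correlation), with the immunoproteasome subunit Psmb9 at 1.01 ± 0.22 (SE). No member was called with the erythroid and neutrophil score as a covariate. Cytosolic heat shock genes rose in 7 of 14 cases (camera adjusted p = 0.017, adjusted p = 0.494 with an estimated correlation), with the small chaperones Cryab and Hspb8 at 1.73 and 1.41. With the muscle score as a covariate 1 member was called, Cryab stood at 0.27 (adjusted p = 0.429) and Hspb8 at 0.63. The heat shock list lost its call with the muscle score (camera adjusted p = 0.126), the erythroid and neutrophil score (0.125) and both (0.657). Antioxidant genes rose in 15 of 23 cases and fell in 4 (15 and 6 adjusted over the list alone; camera adjusted p = 0.0371, adjusted p = 0.51 with an estimated correlation). The extracellular superoxide dismutase Sod3 rose from 80.7 ± 12.6 CPM (SD, n = 7) to 285 ± 68.8 CPM (SD, n = 6). Without aged replicate 6 the list was not called (adjusted p = 0.0658), and with the erythroid and neutrophil score as a covariate 5 members rose and the median moved from 0.44 to −0.027. Interferon response genes rose in 8 of 19 cases and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.0404, adjusted p = 0.51 with an estimated correlation). That call was lost in 6 of 13 fits that left out a library (adjusted p up to 0.0882), those without young replicates 5 and 7 and aged replicates 1, 2, 4 and 6. No interferon gene was called with the erythroid and neutrophil score as a covariate, and the median moved from 0.32 to 0.135. The muscle score also ended the list's call (median 0.23, camera adjusted p = 0.0945). Adipocyte markers rose in 7 of 9 cases and fell in 1 (camera adjusted p = 0.0484, adjusted p = 0.494 with an estimated correlation). That call was kept only without young replicate 1, 2 or 4 or aged replicate 3 and lost in the other 9 fits (adjusted p up to 0.128). With the muscle score as a covariate 1 adipocyte marker rose, while the list median went from 0.71 to 0.53. Vwf, the clotting factor carrier of endothelial cells, rose from 24.4 ± 5.43 to 108.8 ± 27.2 CPM, while the capillary genes Emcn and Plvap fell by 0.73 and 0.63 on the log2 scale. Both lost their calls with the erythroid and neutrophil score as a covariate (−0.32 and −0.61, adjusted p = 0.41 and 0.0571). The endothelial list (1 rose and 5 fell of 14) was not called (camera adjusted p = 0.0806), but with the muscle score as a covariate 11 fell and it was called lower (median −0.62, adjusted p = 0.000157).

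The other lists were not called by camera. Of these, 8 passed the exact permutation test of list means, which does not compare a list with other genes. Higher by that test were complement (adjusted p = 0.00918), macrophage (0.00408), T and NK cell (0.0049), Schwann and neural (0.0118), plasma cell (0.0196) and epithelial lists (0.00204). B cell (0.0297) and sex-linked lists (0.00583) were lower. Complement genes rose in 9 and fell in 2 of 17 cases (camera adjusted p = 0.0627), macrophage markers in 8 and 3 of 14 (0.132), T and NK cell markers in 4 and 1 of 7 (0.109), Schwann and neural markers in 4 and 0 of 12 (0.132) and plasma cell markers in 2 and 2 of 6 (0.866). G2M cell cycle genes rose in 6 and fell in 0 of 22 cases (0.0806), immediate early genes in 6 and 0 of 18 (0.0598), smooth muscle and pericyte markers in 3 and 1 of 12 (0.482) and epithelial markers in 1 and 0 of 5 (0.256). Endoplasmic reticulum folding genes rose in 3 and fell in 7 of 20 cases (0.123), autophagy and lysosome genes in 6 and 3 of 20 (0.718), B cell markers in 0 and 2 of 12 (0.0806), ribosomal protein genes in 0 and 2 of 30 (0.0888) and sex-linked genes in 0 and 2 of 4 (0.179). With library sizes alone the medians of the folding (−0.10 to 0.13), autophagy (−0.03 to 0.20), ribosomal (−0.10 to 0.13), endothelial (−0.22 to 0.01) and sex-linked (−0.19 to 0.04) lists changed sign. The same fit called 6 folding genes higher and 1 lower, and 13 autophagy genes higher and 1 lower. The camera direction of the TGF-beta and BMP list (4 rose and 7 fell of 25) was lower at a median of 0.0077, and that of the autophagy list was higher at a median of −0.03. In the TGF-beta and BMP list 13 members rose and 3 fell with library sizes alone (median 0.23). The cell cycle list depended on the covariate: 12 members rose with the muscle score (median 0.75, camera adjusted p = 2.28e-05) and 16 fell with the erythroid and neutrophil score (median −0.90, camera adjusted p = 1.13e-08). Lists newly called by camera with the muscle score were cell cycle, complement, T and NK cell, macrophage and endothelial. With the erythroid and neutrophil score they were B cell, smooth muscle, Schwann and, turned to lower, cell cycle. The replicate block added cell cycle, complement, B cell and endothelial. Library sizes alone added B cell (camera adjusted p = 0.00177) and endothelial (0.03). Both scores added B cell (0.000119), Schwann (0.00638) and, turned to lower, cell cycle (7.82e-05). Some lists were also newly called with a library left out.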
